A study of Mus musculus with 24 samples.

How the data were processed

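The series measured RNA of whole adrenal glands from mice of 7 months on a mixed sv129 and C57Bl/6 background, with 4 arrays in each of 6 groups (24 arrays). The groups are WT and KO females, WT and KO intact males, and WT and KO males gonadectomised during the last 2 months (GDX). Per the labels, biotinylated cDNA was made from 500 ng of total RNA with the Affymetrix WT PLUS protocol and hybridised to mouse gene arrays. The values are log2 RMA signals as deposited, background-corrected and normalized by the authors, with RMA named per the submitters' processing notes; its software and version are not given in the sources used here. KO mice carried floxed Prkar1a on both alleles and Cre in the Cyp11b2 locus. Per the labels, control females carried 1 floxed allele and Cre, control intact males carried floxed alleles without Cre, and control GDX males carried no Cre (array 1), Cre without a floxed allele (arrays 2 and 3) or Cre with 1 floxed allele (array 4). The labels further give mTmG/mTmG for all mice but that of WT GDX array 2, which was mTmG/+.

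The table holds 32202 probe sets and no missing values. Of these, 22943 carry 1 gene symbol, 1731 several and 7528 none; those with several or none were left out of the tests by gene. The 21957 genes were represented by 1 probe set each, that with the highest mean over the 24 arrays (828 genes have more than 1). Genes whose log2 value was not over 5 in at least 4 arrays were left out as too dim to read, which left 14411. A gene kept this way can still lie under 5 in a whole group, as Akr1c18 did in WT intact males and Bpifc in WT females. The size of such a change is measured against a level too dim to read and is uncertain. Array medians lay between 5.20 and 5.29, single values between 1.88 and 13.40, and 17165 to 17779 probe sets per array stood over 5. Pearson's r between arrays of a group, across probe sets, was 0.974 to 0.993, and the first principal components carried 37.7, 14.9, 7.77 and 5.22% of the variance. No hybridisation or scan batches are used here. Chromosome membership and older symbols were taken from the RefSeq annotation of the assembly GRCm38.p6; the build behind the probe set annotation is not given in the sources used here.

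Each comparison is a contrast in 1 limma model of the 6 group means over all 24 arrays (lmFit and eBayes with default settings, 18 residual and 3.41 prior degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p of 0.05. The contrasts were KO against WT in females, in intact males and in GDX males; female against intact male in WT and in KO; GDX against intact males in WT and in KO; and the interactions of genotype with sex and with gonadectomy. Log2 changes are given ± their standard error from limma. Direction scores took the genes called in one comparison, aligned by sign, and averaged them per array. Arrays outside that comparison were compared by an exact two-sided permutation test of the difference in means (4 against 4, 70 permutations, smallest p 0.0286). These arrays had still entered the filter and the shared estimate of the spread behind the calls. For the sex scores the genes of the X and Y chromosomes were left out.

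The tests of the comparisons, lists and scores, the gene lists and the rule for named genes were fixed before the data were examined. Chosen later were the test of the difference between 2 score effects, the score test within pairs and most tests of explanations. There are 24 lists: steroidogenic core, zona glomerulosa, zona fasciculata and X-zone markers, adrenal androgen synthesis, PKA subunits and phosphodiesterases, CREB and immediate early targets, canonical WNT targets, capsule and mesenchymal progenitors, gonadal-like genes, proliferation, cholesterol synthesis and uptake, glucocorticoid response, androgen response, extracellular matrix, glutathione and oxidative stress, and markers of medulla (chromaffin), endothelial cells, macrophages, lymphocytes, adipocytes, erythrocytes, and Schwann cells and nerve, besides sex chromosome genes. Of 309 list members 266 matched a gene of the table, and 7 symbols stand in more than 1 list. For each list the members called up and down are counted over all genes tested and adjusted over the list alone; where only the first count is printed, both were equal. Where 1 direction is given, 0 members were called in the other. Lists of at least 3 tested members (23) were also tested with camera at the preset correlation of 0.01, adjusted over the lists of a comparison, with the correlation estimated from the residuals beside it (the estimated-correlation adjusted p). Named genes are Prkar1a and Cyp11b2 in every comparison. To these come the called genes with the largest rises and falls and no overlap between the arrays of the groups (10 and 10 in the KO comparisons, 5 and 5 in the others; the interactions without the overlap rule), predicted symbols aside, and up to 4 members per list with the largest changes, of which the text names examples.

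Alternatives tried were no filter and a filter at log2 6, the mean of all probe sets of a gene, another quantile normalization, subtraction of each array's median, eBayes with trend and robust, array weights, a fit of the compared groups alone, the replicate number as a block, and leaving out each array in turn. For the scores they were genes changed at least 2-fold and the median. Added after the data were seen were the adipocyte or the medulla marker mean as a covariate, leaving out both KO GDX arrays 1 and 2, a block within the GDX arrays, and sign changes within their pairs for the score. Whether replicate numbers pair the arrays was checked by correlating the deviations of arrays with the same number from their group means. In KO against WT GDX males all 4 pairs correlated above 0.1 (0.12 to 0.243) and each array correlated best with its own number, so a blocked value is given there. In the other comparisons the pairs ranged from -0.245 to 0.244. Among these, gonadectomy of WT males had positive pairs as well (0.0934 to 0.244), but only 1 of 4 numbers correlated best with its own.

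The tests were run in R 4.3.3 with limma 3.58.1 and the tables and plots made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. They were tested on simulated data of 14411 genes with the spread of these arrays. Of 200 genes changed in KO females 180 were called (74% at a log2 change of 0.5, 94% at 1) with 7 false calls, and of 200 genes with an interaction 158 (48% at 0.5, 84% at 1) with 8 false calls. A comparison with no simulated change gave 0 calls by limma, and camera called the 1 changed list and 0 of 23 unchanged ones. The noise was drawn independently for each gene, so this run does not test camera on lists whose genes vary together. Raw image files were not analysed here.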

Results

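The arrays compare whole adrenal glands of adult mice with and without Prkar1a, the gene of a regulatory subunit that holds protein kinase A inactive. It was removed by a Cre recombinase carried in the locus of Cyp11b2, the aldosterone synthase gene of the zona glomerulosa. Knockout (KO) and control (WT) glands came from females, intact males and gonadectomised males (GDX), with 4 arrays in each of 6 groups. The question put to the data is how the loss of the subunit changes the gland in each sex and after removal of the testes.

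Prkar1a itself was lower in every KO array than in every WT array of the same sex and gonadal state. Its mean log2 level (± SD) was 8.51 ± 0.05 in WT and 7.08 ± 0.32 in KO females, 8.82 ± 0.10 and 7.89 ± 0.69 in intact males, and 8.79 ± 0.16 and 7.60 ± 0.30 in GDX males. The change was -1.43 ± 0.23 (log2 ± standard error, adjusted p 5.83e-05) in females and -1.20 ± 0.23 (adjusted p 0.00477) in GDX males. In intact males it was -0.92 ± 0.23 and did not pass the test (adjusted p 0.16, or 0.0498 without KO array 3), with the 4 KO males at 6.89, 8.08, 8.48 and 8.13. Cyp11b2 fell in KO females (-2.30 ± 0.36, adjusted p 5.11e-05). Its change was -0.95 ± 0.36 in intact males (adjusted p 0.523) and -0.27 ± 0.36 in GDX males (adjusted p 0.737, and 0.03 in place of -0.27 without WT GDX array 1). Per the labels, WT females carried Cre and 1 floxed allele, WT intact males carried no Cre, and the WT GDX males had mixed genotypes. All KO mice carried Cre. Any effect of the Cre insertion on Cyp11b2 or its neighbours is therefore part of the comparison in intact males and of part of that in GDX males. Which part of Prkar1a the probe set covers, relative to the deleted stretch, is not given in the sources used here.

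**Figure D1:**
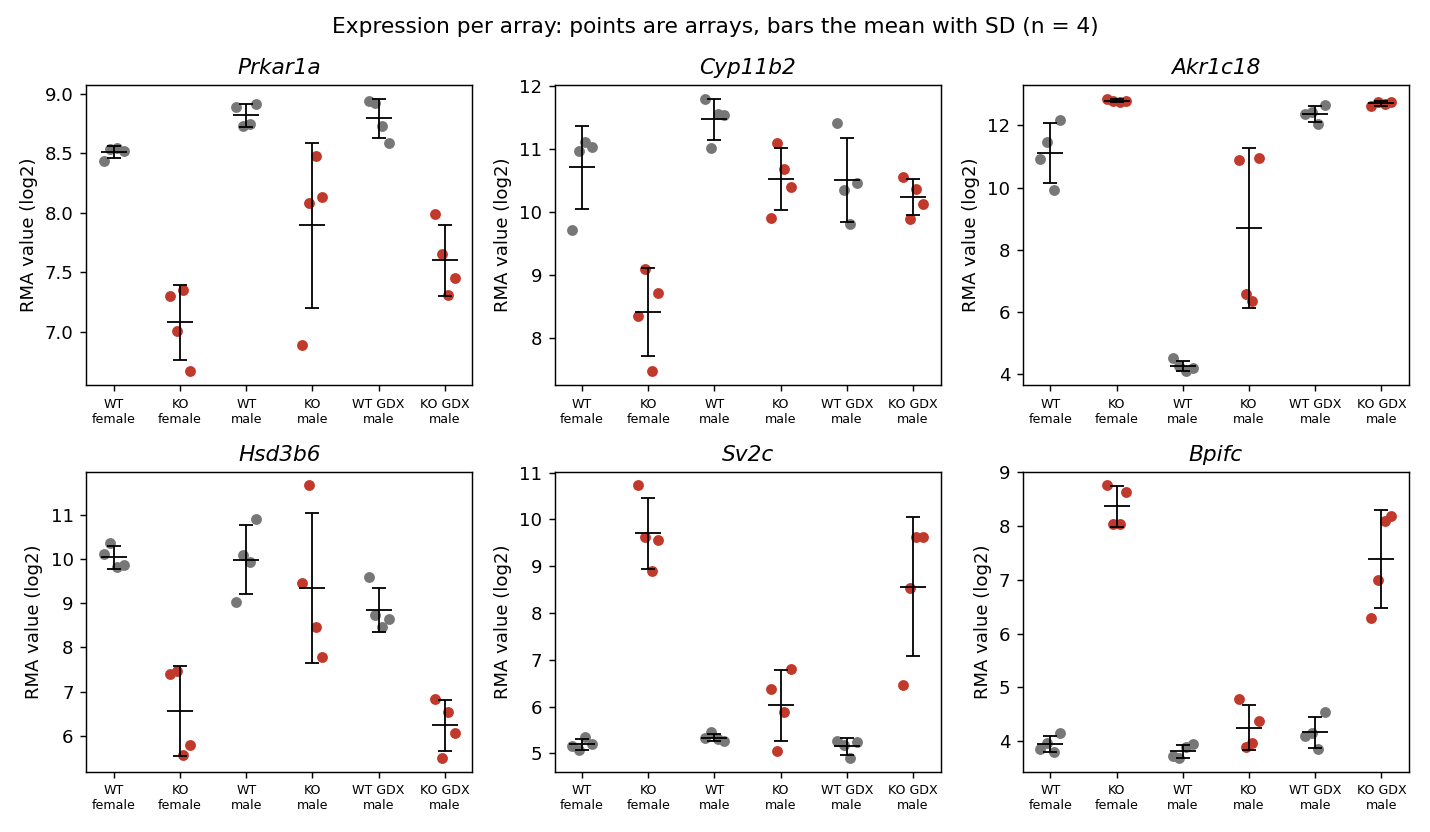
Log2 level (vertical axis, RMA units) of Prkar1a, Cyp11b2, Akr1c18, Hsd3b6, Sv2c and Bpifc in each array of the 6 groups (horizontal axis; points are arrays, bars are means ± SD of 4 arrays). Prkar1a is lower in each KO array than in the WT arrays of its sex and gonadal state, and Akr1c18 spans 6.36 to 10.96 in the KO intact males.

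In females, loss of Prkar1a went with a broad change of the gland. The largest rises were in Sv2c (4.51 ± 0.49, adjusted p 9.05e-07), a synaptic vesicle protein gene, and Bpifc (4.42 ± 0.30, adjusted p 5.91e-09), of the lipid-binding BPI fold family. Both stood above all WT arrays in 4 of 4 KO arrays. Bpifc lay under the filter level of 5 in all WT females, so the size of its rise is uncertain. They were followed by Ptprz1 (4.04), Fetub (3.96), Emb (3.90), Chil3 (3.79), St8sia5 (3.69), Spink8 (3.55), Tgm3 (3.41) and Nxph1 (3.33). The second probe sets of Emb and St8sia5 changed far less (0.24 and 0.23). The largest falls included the glomerulosa genes Vsnl1 (-3.58 ± 0.40, adjusted p 1.08e-06), a neuronal calcium sensor, and Hsd3b6 (-3.48 ± 0.60, adjusted p 0.000156), a 3 beta-hydroxysteroid dehydrogenase. Further falls were in Retn (-2.79), Lgals12 (-2.77), Cdo1 (-2.69), Pnpla3 (-2.52), Car3 (-2.40), Car5b (-2.36) and Cdh6 (-2.25), besides Cyp11b2. Of 14411 genes tested, 4694 were called at adjusted p 0.05, 2001 higher and 2693 lower in KO. Of these 417 changed at least 2-fold. In 32.8% of genes the arrays of the groups did not overlap, against 2.86% by chance.

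In the female KO gland genes of cholesterol synthesis rose while markers of the zona glomerulosa fell. Of the genes of cholesterol synthesis and uptake 15 of 16 rose, 16 adjusted over the list alone, with a median change of 1.42 (camera adjusted p 1.49e-15, estimated-correlation adjusted p 0.0715). Among them were Sqle (2.50 ± 0.25, adjusted p 3.17e-07), squalene epoxidase, Hsd17b7 (2.43), Cyp51 (2.37) and Fdps (2.33). Of steroidogenic core genes 7 of 15 rose (camera adjusted p 0.0108, estimated-correlation adjusted p 0.258). They included Fdx1 (1.25 ± 0.11, adjusted p 1.43e-07), the electron donor of mitochondrial steroid hydroxylases, and Scarb1 (0.93), a receptor that takes up lipoprotein cholesterol. Of zona fasciculata markers 4 of 6 rose (camera adjusted p 0.00517, estimated-correlation adjusted p 0.155), with the list mean of WT array 4 at 11.29 and the other WT females at 11.39 to 11.41. Of these 6 markers 5 also stand in the core list, among them Fdx1 and Mrap (1.21 ± 0.11, adjusted p 1.95e-07), the accessory protein of the ACTH receptor. Only Abcb1b (0.67) is added, so in every comparison this list is largely a part of the core. Of zona glomerulosa markers 9 of 11 fell, with a median of -1.01 (camera adjusted p 8.75e-07, estimated-correlation adjusted p 0.0568). Among them were Vsnl1, Hsd3b6, Cyp11b2 and the potassium channel gene Kcnk9 (-1.84 ± 0.27, adjusted p 2.35e-05). Canonical WNT targets fell as well, in 8 of 10, 9 adjusted over the list alone (camera adjusted p 0.000133, estimated-correlation adjusted p 0.0568). Examples are Wnt4 (-1.01 ± 0.15, adjusted p 2.09e-05), which stands in the glomerulosa list too, and Nkd1 (-0.90). Adrenal androgen synthesis genes rose in 2 of 5, Cyb5a (1.09) and Hsd17b3 (1.30) (camera adjusted p 0.033, estimated-correlation adjusted p 0.0847). Cyp17a1 stood at 1.20 ± 0.57 (adjusted p 0.115, or 0.00146 when the female groups were fitted alone). Its level lay under the filter level of 5 in all WT females (3.98 to 4.50), so the size of its change is uncertain. Akr1c18, the enzyme that inactivates progesterone in the X-zone, stood at 1.67 ± 0.73 (adjusted p 0.0855, or 0.0113 with the female groups fitted alone), and limma called 0 of the 5 X-zone markers.

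Genes of other cells moved in the female glands too. Capsule and mesenchymal progenitor genes fell in 10 of 11 (camera adjusted p 8.75e-07, estimated-correlation adjusted p 0.0641). They included Lum (-1.88 ± 0.31, adjusted p 0.000111), a matrix proteoglycan, Pdgfra (-1.10) and Rspo3 (-1.24), the WNT-enhancing signal of the capsule. Chromaffin markers of the medulla fell in 11 of 15, 12 adjusted over the list alone (camera adjusted p 0.00142, estimated-correlation adjusted p 0.402), such as the vesicular monoamine transporters Slc18a1 (-0.94) and Slc18a2 (-0.88). Adipocyte markers fell in 7 of 10, among them Retn and Car3 named above, which move with these groups (camera adjusted p 0.00277, estimated-correlation adjusted p 0.402). Macrophage markers rose in 4 of 14, 8 adjusted over the list alone (camera adjusted p 0.00361, estimated-correlation adjusted p 0.514), Cd163 (1.20) and Mrc1 (0.88) among them, with the list mean of WT array 1 at 6.66 and the other WT females at 6.93 to 6.96. Among glucocorticoid response genes 7 rose and 1 fell of 12 (camera adjusted p 0.00553, estimated-correlation adjusted p 0.0811), with Ddit4 (0.73) and Lcn2 (1.14) among the rises. Genes of glutathione and oxidative stress rose in 5 of 11 (camera adjusted p 0.00659, estimated-correlation adjusted p 0.0847), such as Srxn1 (0.90) and Txnrd1 (0.71). The WNT, capsule, glomerulosa and cholesterol groups were measured in glands whose medulla list mean fell by 0.52 ± 0.15 and whose adipocyte list mean fell by 1.77 ± 0.41.

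The other lists did not pass in females. PKA subunits and phosphodiesterases went both ways (3 rose and 6 fell of 20, 4 and 6 adjusted over the list alone, adjusted p 0.835), with Adcy6 (-0.87) and Pde2a (-0.65) lower and Pde8a (0.77) higher. So did CREB and immediate early targets (2 rose and 1 fell of 16, adjusted p 0.424), with Sik1 (1.19) higher and Nr4a3 (-0.91) lower. Extracellular matrix genes (2 rose and 4 fell of 13, 2 and 5 adjusted over the list alone, adjusted p 0.201) included Postn (-1.32) and Mmp2 (-1.66). Gonadal-like genes (4 of 8 fell, adjusted p 0.0744) included Esr1 (-0.84), and endothelial markers (2 of 10 fell, 1 adjusted over the list alone, adjusted p 0.318) Cdh5 (-0.50). The mitotic kinase Ttk (1.40) rose and Mcm2 (-0.35) fell among proliferation genes (1 rose and 1 fell of 17, adjusted p 0.318). Steap4 (-1.08) fell among androgen response genes (1 rose and 1 fell of 7, adjusted p 0.893). No member was called by limma among lymphocyte (4 tested; camera adjusted p 0.834), Schwann and nerve (5; 0.834) and erythrocyte markers (1, too few for camera) or among sex chromosome genes (4; 0.657). X-zone markers had a median of -0.11, a mean of 0.22 and an upward camera direction (adjusted p 0.834). Schwann markers had a median of 0.03, a mean of -0.01 and an upward direction. With an estimated correlation camera called 0 of 23 lists in females, 7 of them at an unadjusted p under 0.05. With the medulla marker mean as a covariate, an alternative added after the data were seen, 2173 genes were called in place of 4694. Each KO female lay below each WT female in that mean (8.28 to 8.77 against 8.88 to 9.22). The covariate can therefore also remove part of the difference between these groups. With the medulla covariate 52 of 57 of the named genes called in females kept their call. With the adipocyte mean as a covariate 53 kept it. Those that lost it were Lcn2, Mmp2, Cdh5 and Steap4, and Esr1 lost it when the female groups were fitted alone.

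**Figure D2:**
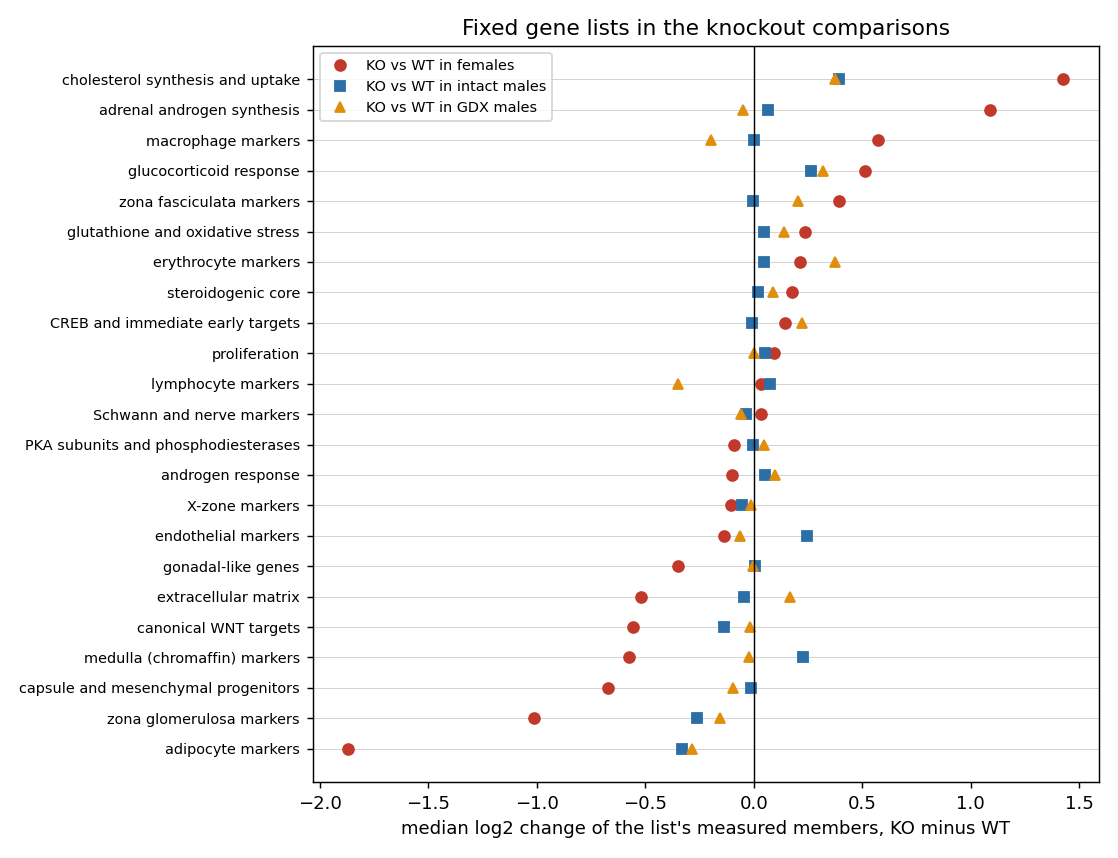
Median log2 change, KO minus WT (horizontal axis), of the measured members of 23 fixed gene lists (vertical axis) in females, intact males and GDX males; each point is 1 list in 1 comparison of 4 against 4 arrays. Cholesterol synthesis lies highest in females (1.42) and adipocyte markers lowest (-1.87).

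In intact males few genes passed the test. Akr1c18 (4.43 ± 0.73, adjusted p 0.0103) rose most, from a mean of 4.26 ± 0.17 (SD) in WT to 8.70 ± 2.58 in KO, with KO males at 10.90, 6.57, 6.36 and 10.96. G6pc (2.35 ± 0.40, adjusted p 0.0145), the catalytic subunit of glucose-6-phosphatase, and Slc6a5 (1.5 ± 0.23, adjusted p 0.00547), a glycine transporter, rose as well. So did Zbtb16 (0.81 ± 0.13, adjusted p 0.0103), a transcription factor induced by glucocorticoids, Inha (0.77 ± 0.12, adjusted p 0.00774), the inhibin alpha subunit, and Bmp4 (0.61 ± 0.09, adjusted p 0.00547), a secreted growth factor. The potassium channel gene Kcnd2 (-1.31 ± 0.19, adjusted p 0.00547) and Mboat1 (-0.92 ± 0.13, adjusted p 0.00547), a lysophospholipid acyltransferase, fell most. Further changes were called in Prrg3 (0.99), Efemp1 (0.51), Fam107a (0.48), Mest (-0.55), Cachd1 (-0.47) and Btbd35f1 (-0.45). In all 16 genes were called, 10 higher and 6 lower in KO (11 and 11 after another round of quantile normalization), and 1080 had an unadjusted p under 0.05. The arrays of the groups did not overlap in 4.46% of genes (2.86% by chance). Fitted on the arrays of these groups alone, limma called 0 genes (1088 at an unadjusted p under 0.05). It called 26 with the adipocyte and 9 with the medulla covariate.

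Glucocorticoid response genes rose as a list in KO intact males, in 1 of 12, 5 adjusted over the list alone, with a median of 0.27. Camera called this list at either correlation (adjusted p 5.08e-07 preset, 0.00508 estimated). Zbtb16 was its called member, while Angptl4 (0.78 ± 0.20) and Cdkn1a (0.72 ± 0.21) had adjusted p 0.199 and 0.304 (Cdkn1a 0.0134 with the adipocyte covariate). Another 7 lists were called with the preset correlation and none of them with the estimated one. Upward these were cholesterol synthesis and uptake (median 0.39, camera adjusted p 5.2e-09, estimated-correlation adjusted p 0.284) and endothelial markers (median 0.24, camera adjusted p 5.08e-07, estimated-correlation adjusted p 0.243), whose list mean in WT array 1 stood at 7.78 and in the other WT males at 8.18 to 8.22. Medulla markers (median 0.23, camera adjusted p 3.27e-05, estimated-correlation adjusted p 0.358) and the steroidogenic core (median 0.02, camera adjusted p 0.0143, estimated-correlation adjusted p 0.343) were called upward too. Zona glomerulosa markers (median -0.26, camera adjusted p 0.00477, estimated-correlation adjusted p 0.29) and WNT targets (median -0.14, camera adjusted p 0.018, estimated-correlation adjusted p 0.284) were called downward, the latter with KO array 1 at 7.50 and the others at 7.64. Adipocyte markers were called downward as well (median -0.33, camera adjusted p 0.0443, estimated-correlation adjusted p 0.858). Adjusted over the list alone, 5 endothelial markers, 2 core genes and 1 cholesterol gene rose, while 2 WNT targets and 1 glomerulosa marker fell.

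Single arrays decided much of the result in intact males. The count was 8 without WT array 3, 9 without WT array 4 and 4 without KO array 1. Of the 14 named genes called, 4 (Slc6a5, Bmp4, Kcnd2 and Mboat1) kept their call whichever array was left out. The call ended for Akr1c18 without KO array 1 (adjusted p 0.067), or with the intact males fitted alone (adjusted p 0.291), and G6pc without WT arrays 2 or 3 or KO array 1 (adjusted p 0.0548 to 0.0684). It ended for Zbtb16 without KO array 1 (adjusted p 0.0684) and Inha without KO array 1 (adjusted p 0.052). Other rises lost it too, Prrg3 without WT arrays 1, 3 or 4 or KO arrays 1 or 2 (adjusted p 0.0537 to 0.118) and Efemp1 without WT arrays 1, 2 or 3 or KO arrays 1 or 3 (adjusted p 0.0736 to 0.195). So did Fam107a without WT arrays 1 or 4 or KO arrays 1 or 2 (adjusted p 0.0602 to 0.139) and, among the falls, Mest without WT arrays 2, 3 or 4 or KO array 1 (adjusted p 0.104 to 0.195). The last were Cachd1 without WT arrays 1, 2, 3 or 4 or KO arrays 1, 3 or 4 (adjusted p 0.071 to 0.195) and Btbd35f1 without WT arrays 2, 3 or 4 or KO arrays 1, 2 or 3 (adjusted p 0.0528 to 0.195).

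In gonadectomised males the knockout changed several of the genes that led in females. Bpifc (3.23 ± 0.30, adjusted p 6.72e-06), Sv2c (3.42 ± 0.49, adjusted p 0.00064), St8sia5 (2.69 ± 0.37, adjusted p 0.000505), a sialyltransferase, and Emb (2.45 ± 0.33, adjusted p 0.000505), a cell adhesion protein, rose, with the second probe sets of St8sia5 and Emb at 0.15 and 0.43. So did Chil3 (2.33), G6pc (2.04), Megf10 (1.94), Ocln (1.83), Apln (2.43) and Rdh1 (1.98). Bpifc lay under the filter level of 5 in all WT GDX males (3.85 to 4.55), so the size of its rise is uncertain. The falls were led by Fa2h (-2.77 ± 0.40, adjusted p 0.000649), fatty acid 2-hydroxylase, Hsd3b6 (-2.62 ± 0.60, adjusted p 0.0162), Ly6d (-2.41 ± 0.44, adjusted p 0.00356) and Acpp (-2.17 ± 0.26, adjusted p 0.000119), prostatic acid phosphatase. Smaller falls were in Kcnd2 (-1.44), Cdh6 (-1.38), Nrep (-1.37), Cpa3 (-1.24), a mast cell carboxypeptidase, and Ms4a14 (-1.15). In total 609 genes were called, 325 higher and 284 lower in KO, with 65 of them changed at least 2-fold. The arrays of the groups did not overlap in 9.63% of genes (2.86% by chance).

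In KO GDX males glucocorticoid response genes rose in 3 of 12, 4 adjusted over the list alone, Zbtb16 (0.86 ± 0.13, adjusted p 0.0011) and Mt1 (0.63 ± 0.12, adjusted p 0.00677), a metallothionein, among them. Camera called the list at either correlation (adjusted p 5.89e-05 preset, 0.025 estimated). Steroidogenic core genes rose in 3 of 15, 5 adjusted over the list alone (camera adjusted p 0.00114, estimated-correlation adjusted p 0.192), among them Mrap (0.76 ± 0.11, adjusted p 0.000838) and Scarb1 (0.78). Zona fasciculata markers rose in 2 of 6, 4 adjusted over the list alone (camera adjusted p 0.000787, estimated-correlation adjusted p 0.149). Genes of cholesterol synthesis and uptake rose in 2 of 16, 5 adjusted over the list alone (camera adjusted p 5.89e-05, estimated-correlation adjusted p 0.587), Dhcr7 (0.78 ± 0.11, adjusted p 0.000505) among them. Glutathione and oxidative stress genes rose in 2 of 11, 4 adjusted over the list alone (camera adjusted p 0.00451, estimated-correlation adjusted p 0.149), such as Srxn1 (0.54). Of zona glomerulosa markers 2 of 11 fell, 3 adjusted over the list alone, Hsd3b6 and Dab2 (-0.39) among them, and the list did not pass (camera adjusted p 0.0783, estimated-correlation adjusted p 0.587).

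The number of genes called in GDX males moved with the arrays used. It was 282 without WT array 2, 289 without WT array 3, 1182 without KO array 1, and 391, 214 and 225 without KO arrays 2, 3 and 4. Fitted on these groups alone it was 49, and 12 of 27 named genes called here kept their call. Array weights gave 1200. The replicate number, which pairs these arrays, gave 551 genes as a block in the fit of all arrays and 721 as a block within the GDX arrays. Leaving out 1 array ended the call of Apln without WT array 2 or KO arrays 3 or 4 (adjusted p 0.0693 to 0.0949) and Rdh1 without WT arrays 2 or 3 or KO arrays 2, 3 or 4 (adjusted p 0.0538 to 0.107). It also ended that of Hsd3b6 without KO arrays 2 or 4 (adjusted p 0.0526 to 0.058) and Cpa3 without WT arrays 2 or 3 or KO arrays 3 or 4 (adjusted p 0.0585 to 0.0782). The others were Ms4a14 without KO arrays 3 or 4 (adjusted p 0.109 to 0.129) and Dab2 without KO arrays 3 or 4 (adjusted p 0.0535 to 0.059).

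Part of the genes called in KO females, such as Bpifc, Sv2c and Hsd3b6, were called in the same direction in KO GDX males. Of 2001 genes higher in KO females, 262 were also called higher in GDX males (45.1 under independence), and of 2693 lower genes 205 were called lower (53.1). In each direction 3 were called the opposite way. Of the 4694 female genes, 85.5% had a change of the same sign in GDX males and 58.8% in intact males, with slopes through 0 of 0.37 and 0.122. Across genes, which are not independent replicates, the changes of females and GDX males gave Pearson's r 0.63 and Spearman's rho 0.54. Those of females and intact males gave 0.29 and 0.13, with 4 shared higher and 5 shared lower calls (1.39 and 1.12 under independence). Intact and GDX males shared 7 of the higher genes (0.226 under independence) and 3 of the lower genes (0.118), Zbtb16, G6pc and Kcnd2 among them. As a score per array (mean of sign-aligned log2 values), the female genes differed by 0.18 ± 0.046 between KO and WT GDX males (exact two-sided permutation p 0.0286, the smallest that 70 permutations give). The replicate numbers pair these arrays, and the 4 pair differences were all positive (0.080 to 0.249, mean 0.182 ± 0.036). With 4 pairs the exact test by sign changes within pairs cannot pass (smallest p 0.125), and no other test within pairs was run. In intact males the difference was 0.04 ± 0.036 (exact p 0.2). The difference of these effects, tested by itself, was 0.14 ± 0.058 (exact p 0.112 over 4900 permutations). In GDX males the score difference lost its call without any of the WT arrays 1 to 4 (0.174, 0.183, 0.172 and 0.198, exact p 0.0571 each).

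**Figure D3:**
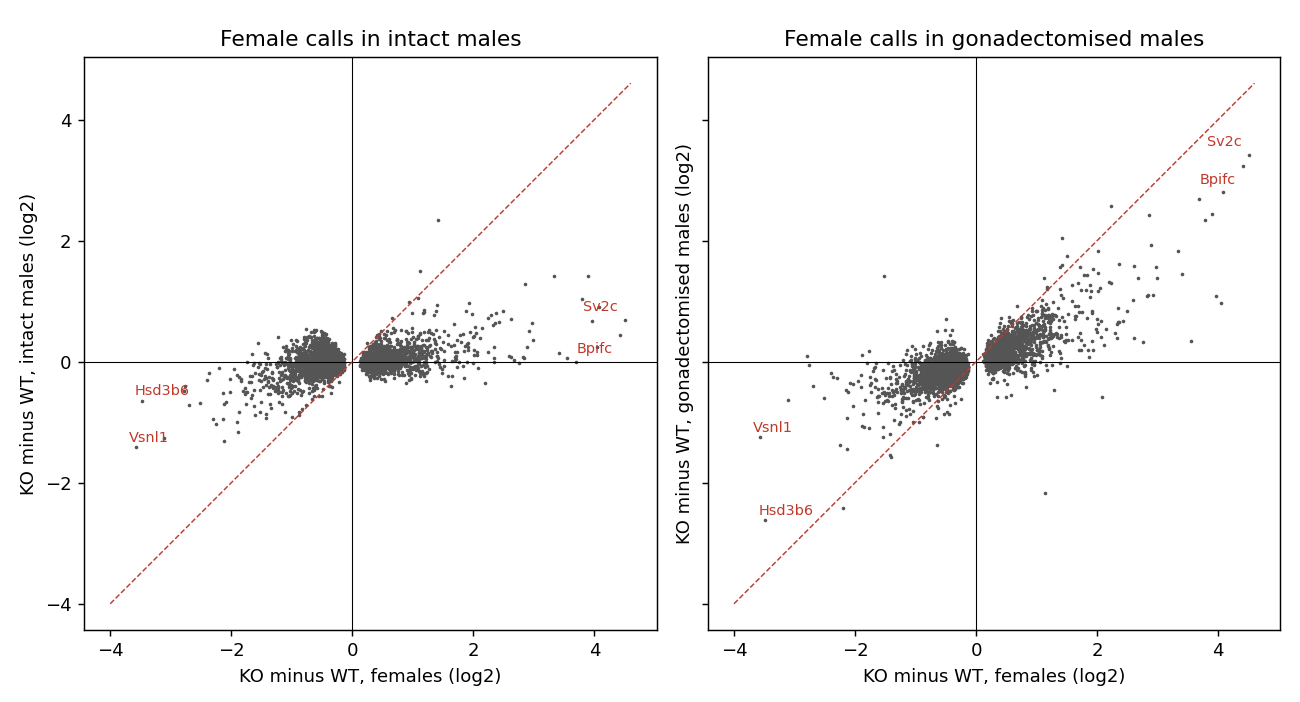
Log2 change, KO minus WT, of the 4694 genes called in females (horizontal axis) against their change in intact males (left) and GDX males (right; vertical axes); each point is 1 gene and the dashed line marks equality. Of these genes 58.8% have the same sign in intact males and 85.5% in GDX males.

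Between the sexes, WT glands differed in X-zone genes and in genes of the sex chromosomes. The X-zone markers Akr1c18 (6.86 ± 0.73, adjusted p 3.35e-06), Akr1d1 (6.42 ± 0.69, adjusted p 3.38e-06), a steroid 5 beta-reductase, Cyp2f2 (4.06 ± 0.56, adjusted p 6.68e-05) and Thrb (1.06), the thyroid hormone receptor beta gene, were higher in females. The list was higher in 4 of 5, 5 adjusted over the list alone, and camera called it at either correlation (adjusted p 4.61e-09 preset, 0.00524 estimated). Frzb (5.36 ± 0.31, adjusted p 1.26e-10), a secreted WNT inhibitor, was higher in females as well. Acan (-2.80 ± 0.43, adjusted p 0.000222), the cartilage proteoglycan aggrecan, and St8sia5 (-2.72 ± 0.37, adjusted p 5.97e-05) were higher in males. The second probe sets of Cyp2f2 and St8sia5 stood at 0.80 and -0.32. The X-linked Xist (6.98) and the Y-linked Uty (-5.07), Eif2s3y (-4.59) and Kdm5d (-3.96) parted the sexes in all arrays (camera adjusted p 4.18e-06, estimated-correlation adjusted p 0.0137). Nr0b1 (2.60 ± 0.59), the nuclear receptor DAX-1, was higher in females. Gonadal-like genes were higher in 3 of 8, 4 adjusted over the list alone (camera adjusted p 0.0192, estimated-correlation adjusted p 0.336), Esr1 (0.76) and Gata4 (0.50) among them. Single arrays ended the call of Esr1 without WT female arrays 3 or 4 or WT intact male arrays 1, 2, 3 or 4 (adjusted p 0.0567 to 0.134) and Gata4 without WT female arrays 1, 3 or 4 or WT intact male arrays 3 or 4 (adjusted p 0.0601 to 0.0951). Prkar1a (-0.31 ± 0.23, adjusted p 0.456, or 0.0253 when these groups were fitted alone) and Cyp11b2 (-0.77 ± 0.36, adjusted p 0.215) did not pass. In total 1117 genes were called, 538 higher in females and 579 higher in males (1958 with array weights). Of these 136 changed at least 2-fold, and 15.2% of genes had no overlap (2.86% by chance). The WT females carried Cre and 1 floxed allele, the WT intact males 2 floxed alleles and no Cre, so sex and control genotype change together here.

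In KO glands, which share 1 genotype, the sexes differed in many groups. X-zone markers were again higher in females (5 of 5 higher, camera adjusted p 0.000363, estimated-correlation adjusted p 0.0987). So were Fetub (5.10 ± 0.41, adjusted p 1.53e-08), the fetuin-B gene, Obp2a (4.62 ± 0.76, adjusted p 5.53e-05) and Frzb (5.08). The sex-linked Xist (6.86), Uty (-4.84), Eif2s3y (-4.76) and Kdm5d (-3.74) parted the sexes (camera adjusted p 0.00752, estimated-correlation adjusted p 0.154). Aldh1a1 (-3.34 ± 0.53, adjusted p 3.65e-05), a retinaldehyde dehydrogenase, and Acan (-3.16 ± 0.43, adjusted p 6.93e-06) were lower in KO females. Cholesterol genes were higher in KO females (15 of 16 higher, camera adjusted p 2.41e-09, estimated-correlation adjusted p 0.176), such as Hsd17b7 (2.21) and Cyp51 (1.86). Core genes went both ways (8 higher and 1 lower of 15, camera adjusted p 0.0287, estimated-correlation adjusted p 0.308). Zona glomerulosa markers were lower (9 of 11 lower, camera adjusted p 2.78e-05, estimated-correlation adjusted p 0.0987), with Cyp11b2 at -2.12, Hsd3b6 at -2.78 and Kcnk9 at -2.26. WNT targets (9 of 10 lower, camera adjusted p 0.000363, estimated-correlation adjusted p 0.0987) and capsule genes (9 of 11 lower, 10 adjusted over the list alone, camera adjusted p 2.44e-05, estimated-correlation adjusted p 0.104) were lower. Medulla markers were lower (13 of 15 lower, camera adjusted p 2.84e-06, estimated-correlation adjusted p 0.234), Penk (-1.62) among them, as were endothelial markers (8 of 10 lower, camera adjusted p 0.00978, estimated-correlation adjusted p 0.393). Prkar1a was lower in KO females than in KO males (-0.81 ± 0.23, adjusted p 0.00596). In all 5906 genes were called, 2570 higher in females and 3336 higher in males, with no overlap in 36.6% of genes (2.86% by chance). With the medulla mean as a covariate 417 were called. Each KO female lay below each KO male in that mean (8.28 to 8.77 against 9.33 to 9.56), so the covariate also removes the difference between these groups. With it 6 of 16 named genes called here kept their call.

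**Figure D4:**
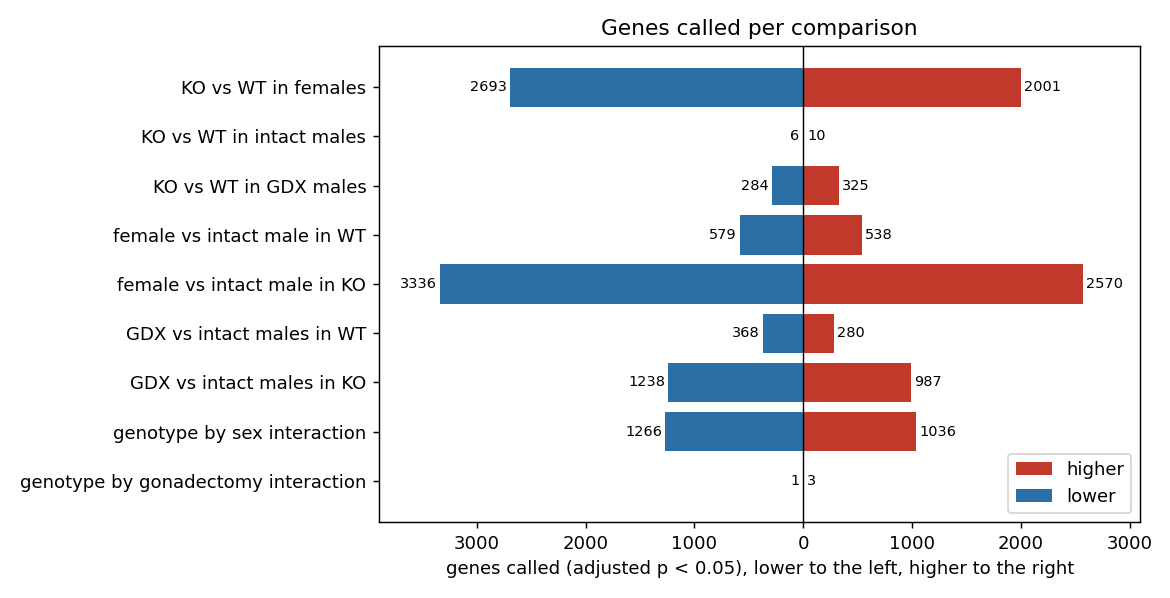
Number of genes called at adjusted p 0.05 (horizontal axis), higher to the right and lower to the left, in each of the 9 comparisons (vertical axis) of 14411 genes. Most were called between KO females and KO intact males (5906) and fewest in the genotype by gonadectomy interaction (4).

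Gonadectomy of WT males raised X-zone genes, Akr1c18 and Akr1d1 above all others. Akr1c18 (8.11 ± 0.73, adjusted p 1.28e-06) went from 4.26 ± 0.17 to 12.37 ± 0.25, and Akr1d1 (5.91 ± 0.69, adjusted p 2.57e-05), Cyp2f2 (2.78 ± 0.56, adjusted p 0.00651) and Thrb (1.10) rose with it. The level of Akr1c18 in WT intact males lies under the filter level of 5, so the size of its rise is uncertain. Of the X-zone list 4 of 5 rose, 5 adjusted over the list alone (camera adjusted p 2.17e-11 preset, 0.00154 estimated). The list mean of WT GDX array 2 was 11.05 and that of the others 10.35 to 10.38. Hamp (4.05 ± 0.82, adjusted p 0.00648), hepcidin, Fa2h (3.99 ± 0.40, adjusted p 4e-06) and Fetub (3.71 ± 0.41, adjusted p 1.34e-05) rose too. Acan (-2.59 ± 0.43, adjusted p 0.00138), Serpina6 (-2.27 ± 0.24, adjusted p 5.94e-06), corticosteroid-binding globulin, Susd3 (-1.85), St6galnac2 (-1.44) and St8sia5 (-1.61) fell. The second probe sets of Cyp2f2 and St8sia5 stood at 0.44 and -0.22. Proliferation genes were called upward with the preset correlation (1 of 17 rose, 11 adjusted over the list alone, camera adjusted p 1.76e-07, estimated-correlation adjusted p 0.404), Ccna2 (0.89) among them. Of CREB and immediate early targets 2 rose and 1 fell of 16, 4 and 1 adjusted over the list alone (camera adjusted p 0.0136, estimated-correlation adjusted p 0.837), with the list mean of WT GDX array 1 at 7.37 and the others at 7.70 to 7.74. Zona glomerulosa markers were called downward (1 of 11 fell, 6 adjusted over the list alone, camera adjusted p 0.0052, estimated-correlation adjusted p 0.404), as were WNT targets (1 of 10 fell, 4 adjusted over the list alone, camera adjusted p 0.0052, estimated-correlation adjusted p 0.19), with Lef1 (-0.50) in both lists. The glomerulosa mean of WT GDX array 1 was 8.68 and that of the others 8.34 to 8.38. Adipocyte markers had no called member but a median of 0.64 (camera adjusted p 0.0202, estimated-correlation adjusted p 0.837). Prkar1a (-0.02 ± 0.23, adjusted p 0.974, and above 0 without WT intact male array 4, at 0.008, or WT GDX array 4, at 0.04) and Cyp11b2 (-0.97 ± 0.36, adjusted p 0.137, but -1.27, adjusted p 0.0417, without WT GDX array 1) did not pass.

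Of the genes tested, 648 were called after gonadectomy of WT males, 280 higher and 368 lower, with no overlap in 9.29% of genes (2.86% by chance). The count was 386, 306 and 295 without WT intact male arrays 2, 3 and 4, 312 and 354 without WT GDX arrays 2 and 3, and 149 when these groups were fitted alone. Single arrays ended the call of St8sia5 without WT intact male array 4 or WT GDX array 3 (adjusted p 0.0568 to 0.0606), Lef1 without WT intact male array 3 or WT GDX array 4 (adjusted p 0.0515 to 0.0637) and Ccna2 without WT intact male arrays 1, 2, 3 or 4 or WT GDX arrays 1, 2 or 3 (adjusted p 0.0555 to 0.15). WT intact males had no Cre and the WT GDX males mixed genotypes, which change together with gonadectomy. The same WT intact males serve in the comparison of WT sexes.

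Gonadectomy of KO males, all of 1 genotype, also raised X-zone markers. Akr1d1 (5.98 ± 0.69, adjusted p 1.83e-05), Akr1c18 (4.00 ± 0.73, adjusted p 0.00107), Cyp2f2 (2.48, its second probe set 0.15) and Thrb (1.14) rose. Of the list 4 of 5 rose (camera adjusted p 1.42e-05 preset, 0.0476 estimated). Fetub (4.12 ± 0.41, adjusted p 4.25e-06), Obp2a (3.71 ± 0.76, adjusted p 0.00259), an odorant-binding protein gene, and Serpinb1a (3.54 ± 0.54, adjusted p 0.00022), an inhibitor of neutrophil proteases, rose too. Hsd3b6 (-3.11 ± 0.60, adjusted p 0.00165), Acan (-2.88 ± 0.43, adjusted p 0.000175), Aldh1a1 (-2.67), Ly6d (-2.58) and Serpina6 (-1.94) fell. Endothelial markers fell in 5 of 10 (camera adjusted p 0.00084, estimated-correlation adjusted p 0.539), such as Emcn (-0.56) and Tek (-0.54). Medulla markers fell in 5 of 15, 6 adjusted over the list alone (camera adjusted p 0.0113, estimated-correlation adjusted p 0.539), Penk (-0.80) among them. Capsule genes fell beside them in 3 of 11, 5 adjusted over the list alone (camera adjusted p 0.0225, estimated-correlation adjusted p 0.539), with Rspo3 (-0.65), and zona glomerulosa markers in 3 of 11, 6 adjusted over the list alone (camera adjusted p 0.0225, estimated-correlation adjusted p 0.539). Proliferation genes rose in 3 of 17, 5 adjusted over the list alone (camera adjusted p 0.000297, estimated-correlation adjusted p 0.539), Ttk (0.65) among them, with the list mean of KO GDX array 2 at 6.72 and the others at 5.82 to 5.89. CREB targets rose in 3 of 16 (camera adjusted p 0.00391, estimated-correlation adjusted p 0.539), Egr1 (1.22) among them, with KO GDX array 1 at 8.89 and the others at 7.35 to 7.57. Adipocyte markers rose in 2 of 10, 3 adjusted over the list alone (camera adjusted p 0.0113, estimated-correlation adjusted p 0.539) and cholesterol genes in 1 of 16 (camera adjusted p 0.0495, estimated-correlation adjusted p 0.736), Dhcr7 (0.39). Prkar1a (-0.29 ± 0.23, adjusted p 0.414, but -0.63, adjusted p 0.00988, without KO intact male array 1) and Cyp11b2 (-0.29 ± 0.36, adjusted p 0.64) did not pass. Of 2225 genes called, 987 were higher and 1238 lower (no overlap in 19.0% of genes, 2.86% by chance). The count was 1414 and 1465 without KO intact male arrays 2 and 3, and 1374 without KO GDX array 3. With the medulla covariate it was 774 and with array weights 3599. Single arrays ended the call of Penk without KO intact male arrays 1, 2 or 3 or KO GDX array 3 (adjusted p 0.0569 to 0.0644) and Dhcr7 without KO intact male array 2 or KO GDX arrays 2 or 4 (adjusted p 0.0606 to 0.0775), and the call of Egr1 ended without both KO GDX arrays 1 and 2 (adjusted p 0.105).

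Genes that differ between WT females and WT males moved towards the female level after gonadectomy of KO males, on arrays outside the comparison that chose them. Over the 1064 autosomal genes called between the WT sexes, the score rose from -0.32 in KO intact males to 0.06 in KO GDX males (difference 0.38 ± 0.047, exact two-sided permutation p 0.0286), against 0.27 in WT females and -0.34 in WT males. Over the 5668 autosomal genes called between the KO sexes, WT GDX males lay above WT intact males by 0.13 ± 0.040, short of the threshold (exact p 0.0571). Without WT intact male array 1 this difference was 0.165 (exact p 0.0286). Among the same WT sex genes KO and WT GDX males differed by -0.0026 ± 0.030 (exact p 0.886).

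**Figure D5:**
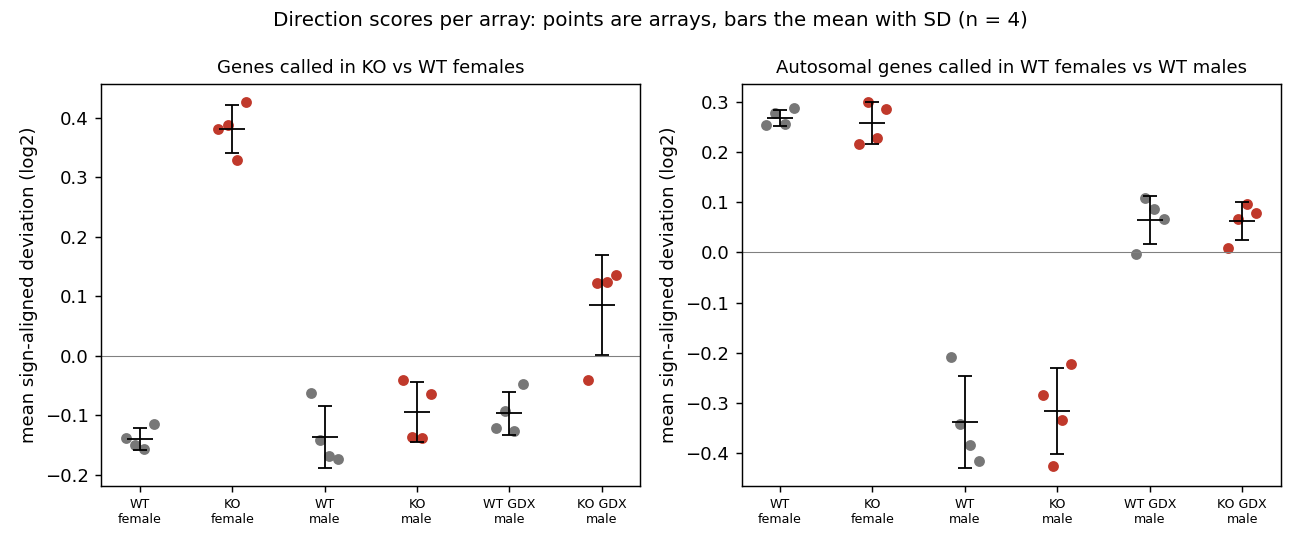
Score per array (vertical axis, mean of sign-aligned log2 values) of the 4694 female knockout genes (left) and the 1064 WT sex genes (right) in the 6 groups (horizontal axis); points are arrays, bars means ± SD of 4 arrays. KO GDX males lie at 0.09 in the left panel, against -0.10 in WT GDX males, and both GDX groups lie near 0.06 in the right panel.

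Tested as an interaction, the knockout effect differed between females and intact males in many of the genes above. It was more positive in females for Bpifc (3.98 ± 0.43, adjusted p 3.07e-05), Sv2c (3.82 ± 0.69, adjusted p 0.00126), Ptprz1 (3.79 ± 0.53, adjusted p 0.000209), a receptor tyrosine phosphatase, St8sia5 (3.69 ± 0.52, adjusted p 0.000225) and Spink8 (3.48). The second probe set of St8sia5 stood at 0.36. Bpifc lay under the filter level of 5 in all WT females and all intact males, so the size of its interaction is uncertain. The knockout effect was more negative in females for Vsnl1 (-2.16 ± 0.56, adjusted p 0.0128), Retn (-2.30 ± 0.52, adjusted p 0.0059), Hsd3b6 (-2.83), Lgals12 (-2.37) and Car5b (-2.18). Cholesterol genes were called upward (12 of 16 more positive, 14 adjusted over the list alone, camera adjusted p 1.4e-10, estimated-correlation adjusted p 0.151), such as Sqle (1.66) and Hsd17b7 (1.77). So were zona fasciculata markers (3 of 6 more positive, camera adjusted p 0.00531, estimated-correlation adjusted p 0.171), with Mrap (1.11). Glutathione genes (2 of 11 more positive, 3 adjusted over the list alone, camera adjusted p 0.00836, estimated-correlation adjusted p 0.143) and macrophage markers (1 of 14 more positive, camera adjusted p 0.00715, estimated-correlation adjusted p 0.621) were called upward too. Zona glomerulosa markers were called downward (8 of 11 more negative, 9 adjusted over the list alone, camera adjusted p 3.5e-05, estimated-correlation adjusted p 0.139), with Kcnk9 (-1.52). WNT targets, Lgr5 (-1.12) among them, went the same way (6 of 10 more negative, 6 more negative and 1 more positive adjusted over the list alone, camera adjusted p 0.00423, estimated-correlation adjusted p 0.139). Capsule genes did as well (8 of 11 more negative, camera adjusted p 1.17e-06, estimated-correlation adjusted p 0.139), with Pdgfra (-1.36) and Rspo3 (-1.22). Medulla markers, which move with these groups, were called downward (11 of 15 more negative, 13 adjusted over the list alone, camera adjusted p 3.24e-06, estimated-correlation adjusted p 0.22), Slc18a1 (-1.19) among them. The same holds for endothelial (2 of 10 more negative, 7 adjusted over the list alone, camera adjusted p 0.00345, estimated-correlation adjusted p 0.308; WT intact male array 1 stood apart in this list) and adipocyte markers (3 of 10 more negative, 4 adjusted over the list alone, camera adjusted p 0.0297, estimated-correlation adjusted p 0.621). Neither Prkar1a (-0.50 ± 0.32, adjusted p 0.305) nor Cyp11b2 (-1.35 ± 0.51, adjusted p 0.0728) passed this test. Without KO intact male array 1 both did (-0.84, adjusted p 0.011, and -1.55, adjusted p 0.0458), and Cyp11b2 also without WT female array 1 (-1.68, adjusted p 0.0229) or KO female array 2 (-1.58, adjusted p 0.0459).

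The interaction with sex called 2302 genes, 1036 more positive and 1266 more negative in females, 291 of them by at least 2-fold. With the medulla covariate 143 were called, and 6 of 18 named genes called here kept their call. In the medulla mean each KO female (8.28 to 8.77) lay below each WT female (8.88 to 9.22) and each KO intact male (9.33 to 9.56). The covariate can therefore also remove part of the interaction itself. The control females carried Cre and 1 floxed allele and the control intact males 2 floxed alleles without Cre, so this difference includes that of the control genotypes. Single arrays ended the call of Hsd3b6 without WT female array 2, KO female arrays 3 or 4 or WT intact male array 1 (adjusted p 0.0523 to 0.0666), Lgals12 without WT female array 2, KO female arrays 2 or 4, WT intact male arrays 1 or 4 or KO intact male arrays 1 or 3 (adjusted p 0.0516 to 0.0669) and Car5b without WT female array 2, WT intact male array 1 or KO intact male array 1 (adjusted p 0.0507 to 0.0582). With the estimated correlation camera called 0 of 23 lists here, 6 of them at an unadjusted p under 0.05, where the preset correlation called 10.

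The interaction with gonadectomy called 4 genes, with 1361 at an unadjusted p under 0.05. The knockout effect was more positive in GDX than in intact males for Bpifc (2.79 ± 0.43, adjusted p 0.0117), Ceacam1 (1.5 ± 0.25, adjusted p 0.02), a cell adhesion gene, and Eda (0.64 ± 0.11, adjusted p 0.02), ectodysplasin A, and more negative for Acpp (-2.42 ± 0.37, adjusted p 0.0117). Bpifc lay under the filter level of 5 in all intact males and all WT GDX males, so the size of its interaction is uncertain. Akr1c18 stood at -4.10 ± 1.04 (adjusted p 0.181), Prkar1a at -0.27 ± 0.32 (adjusted p 0.85) and Cyp11b2 at 0.68 ± 0.51 (adjusted p 0.73). With the preset correlation camera called endothelial markers downward (median -0.25, camera adjusted p 0.000941, estimated-correlation adjusted p 0.431), the list in which WT intact male array 1 stood apart. It called zona fasciculata markers (median 0.13, camera adjusted p 0.0169, estimated-correlation adjusted p 0.431) and glutathione genes (median 0.18, camera adjusted p 0.0169, estimated-correlation adjusted p 0.431) upward. Adjusted over the list alone limma called 2 fasciculata markers and 1 glutathione gene. With the estimated correlation camera called 0 of 23 lists, 1 of them at an unadjusted p under 0.05. Array weights gave 45 genes, the groups alone 9, the adipocyte covariate 13, the medulla covariate 2, and leaving out both KO GDX arrays 1 and 2 gave 80. The count was 7 and 2 without KO intact male arrays 2 and 3, 30 and 2 without WT GDX arrays 1 and 2, and 88, 2 and 2 without KO GDX arrays 1, 3 and 4. Bpifc and Acpp kept their call whichever array was left out. The call ended for Ceacam1 without KO intact male array 3, WT GDX arrays 2 or 3 or KO GDX arrays 3 or 4 (adjusted p 0.0614 to 0.0791) and Eda without WT intact male arrays 3 or 4, KO intact male arrays 1 or 3, WT GDX array 2 or KO GDX arrays 3 or 4 (adjusted p 0.0517 to 0.0791).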

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

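The tests of the Prkar1a loss, of the medulla share, of a female gland, of X-zone tissue and of dilution by cortical cells were chosen only after the results they weigh were seen, as were both marker covariates and the count of splits in GDX males by pairs; the tests of control genotype, of a gonadectomised gland and, with the covariate added then, of adipose tissue were set before their own values were seen.

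The knockout effect differed between females and intact males in 2302 genes by the interaction test, led by Bpifc (3.98), Sv2c (3.82), Ptprz1 (3.79), St8sia5 (3.69) and Spink8 (3.48) upward and Hsd3b6 (-2.83), Lgals12 (-2.37), Retn (-2.30), Car5b (-2.18) and Vsnl1 (-2.16) downward. A smaller loss of Prkar1a in intact males is argued against as the whole cause if responses scale with the loss: over 608 genes called in GDX males, the response of intact males was 0.203 of that of females (0.152 to 0.236 without single arrays), and the loss 0.753 of theirs (0.534 to 0.859). Each loss was taken against its own controls, which differ: Cre and 1 floxed allele in females, no Cre in intact males. A smaller share of medulla in KO females is argued against as the whole cause for the cholesterol genes, if lists of the cortex follow that share alike. Their interaction exceeded that of the steroidogenic core by 0.97 (0.855 to 1.07), although the medulla covariate left 143 calls. Less adipose tissue is argued against by 2175 calls with its covariate, 1837 of them shared. Control genotype cannot be told apart from sex: over the 608 genes WT females minus WT males was -0.0087 (-0.024 to 0.014), but Cre and sex change together in the WT groups, so opposite effects of both could cancel. A difference of the sexes in the response to the knockout, the biological explanation in the design, stays open.

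Akr1c18 stood at 10.90, 6.57, 6.36 and 10.96 in the 4 KO intact males, against 4.10 to 4.51 in WT intact males. A female gland among them is argued against by Xist, whose lowest female value lay 6.66 above the highest of these males. A gonadectomised gland is argued against by the score of 644 genes that gonadectomy changed in WT, which in the lowest GDX array lay 0.346 above the highest KO intact male. Among the KO intact males that score was higher in arrays 1 and 4 (-0.33 and -0.28) than in arrays 2 and 3 (-0.51 and -0.39). WT intact male array 1, with Akr1c18 at 4.51, scored higher still (-0.22). Whether a partial shift of this score goes with Akr1c18 was not tested. X-zone tissue kept as such cannot be told apart with 4 arrays: the slopes of Akr1d1, Cyp2f2 and Thrb on Akr1c18 among them, scaled by the sex differences, had a mean of 0.341 (0.17 to 0.503 without single arrays, where kept tissue needs at least 0.5), in place of a first measure on group means (-0.053) that does not test a spread between arrays, and KO array 4 had Akr1d1 at 7.99 and Thrb at 8.29, KO array 1 Akr1d1 at 4.13, and WT array 1 Akr1d1 at 8.39. That the knockout raises Akr1c18 by itself to different degrees is a hypothesis these data leave open.

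In KO females the markers of medulla (-0.52 ± 0.15) and capsule (-0.77 ± 0.058) were lower, beside endothelial markers (-0.15 ± 0.046), while macrophage markers were higher (0.55 ± 0.23; list means, KO minus WT). The test assumes that dilution by more cortical cells lowers all other cells alike. Under it dilution is argued against as the whole cause for the capsule, which fell beyond endothelial markers (-0.62, exact two-sided permutation p 0.0286). Whether endothelial cells are diluted like those of the capsule was not tested. For the medulla dilution cannot be told apart, since the difference (-0.37, exact p 0.0571) misses the threshold. Endothelial markers replaced Schwann markers as the measure after the latter were seen to lie low; against Schwann markers the differences were -0.51 for medulla and -0.76 for capsule (exact p 0.0286 each). Less adipose tissue on the KO glands is argued against for the medulla, whose list median was -0.63 with the adipocyte covariate and -0.57 without. The capsule median was -0.62 with that covariate and -0.67 without. The endothelial median was 0.015 with it and -0.14 without, so the fall of the endothelial measure did not stay.

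In each pairwise comparison but KO in GDX males, the real grouping called more genes than any other of the 35 splits of its 8 arrays. In each, 1 split was as large, the real one. Chance can be excluded there, other than for KO in intact males. The real count and the highest of the other splits were 4694 and 80 for KO in females, 16 and 10 in intact males, 1117 and 1 for sex in WT, 5906 and 418 for sex in KO, 648 and 121 for gonadectomy in WT and 2225 and 558 in KO. For gonadectomy in WT the splits took no account of the replicate numbers, whose pairs correlated positively there too (0.0934 to 0.244). For the 16 of intact males the splits do not tell whether chance can be excluded. The 16 fell to 4 without KO array 1, 8 without WT array 3 and 9 without WT array 4, under the 10 of another split. With these groups fitted alone they fell to 0. In GDX males, where the numbers pair the arrays, 8 splits part all 4 pairs, too few for a share under 0.05; the real one called 609 genes and the highest other of the 8 called 15, while the splits that keep some pairs together called 0 to 106. For the interaction with sex, 4 of 100 splits called at least 2302 genes, and the highest, with 6 arrays relabelled, called 4394. For the interaction with gonadectomy (4 genes: Bpifc 2.79, Ceacam1 1.5, Eda 0.64 and Acpp -2.42) 8 of 100 splits called as many, the highest 843 with 10 arrays relabelled. These splits exchanged females with intact males, or GDX with intact males, within each genotype. An uneven exchange carries the difference of sex or gonadectomy itself into the interaction. These counts therefore do not tell whether chance can be excluded for either interaction.

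Single arrays lay apart from the other 3 of their group, by a Dixon ratio above its critical value for 4 values, in 22 of 210 pairs of group and measure, where chance gives about 10.5 (1 in 20); the measures are not independent of each other. In WT females these were array 1 for Cyp11b2 (9.71, others 10.97 to 11.11), macrophage markers (6.66) and Schwann markers (5.97), array 2 for capsule genes (7.69), array 3 for proliferation (5.53) and array 4 for fasciculata markers (11.29). In WT intact males they were array 1 for endothelial markers (7.78) and array 2 for macrophage markers (7.53). In KO intact males they were array 1 for androgen synthesis (6.53) and WNT targets (7.50), array 2 for fasciculata markers (11.46) and array 4 for androgen response (7.24). In WT GDX males they were array 1 for Cyp17a1 (7.64, others 4.34 to 4.88), CREB targets (7.37) and glomerulosa markers (8.68), and array 2 for X-zone markers (11.05). In KO GDX males they were array 1 for androgen synthesis (6.89), CREB targets (8.89, others 7.35 to 7.57), the score of female knockout genes (-0.040, others 0.122 to 0.136) and that of KO sex genes (-0.034), and array 2 for erythrocyte markers (6.69, others 4.78 to 5.05) and proliferation (6.72).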

How the results depend on the processing

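The settings with a marker covariate, without both KO GDX arrays 1 and 2, with a block within the GDX arrays and with the score tested within pairs were chosen only after the results were seen. Counts of genes called stayed within 1.5 times those reported under all other settings tried except those named here, for which the cause was not tested unless fewer arrays or genes enter. Array weights gave 1200 for KO in GDX males, 1958 for sex in WT, 3599 for gonadectomy in KO and 45 for the interaction with gonadectomy. Fits of the compared groups alone, which have fewer arrays to estimate the spread, gave 0 for KO in intact males (limma; 1088 at an unadjusted p under 0.05), 49 for KO in GDX males, 149 for gonadectomy in WT and 9 for the interaction with gonadectomy. The adipocyte covariate gave 26 for KO in intact males and 13 for the interaction with gonadectomy. The medulla covariate gave 2173 for KO in females, 9 in intact males, 417 for sex in KO, 774 for gonadectomy in KO, and 143 and 2 for the interactions with sex and gonadectomy. KO females lay below all WT females and all KO intact males in that covariate, which can remove part of their differences. Without both KO GDX arrays 1 and 2 the interaction with gonadectomy gave 80. With the replicate number as a block no comparison moved by 1.5 times. Leaving out 1 array gave 4 to 24 for KO in intact males, 214 to 1182 in GDX males, 295 to 788 for gonadectomy in WT, 1374 to 2663 in KO and 2 to 88 for the interaction with gonadectomy. It gave 3872 to 4553 for KO in females, 757 to 1315 for sex in WT, 5197 to 5862 in KO and 1615 to 2477 for the interaction with sex. With the estimated correlation camera called 0 lists in place of 12 for KO in females, 1 in place of 8 in intact males, 1 in place of 5 in GDX males, 0 in place of 9 for sex in KO, 1 in place of 6 and 1 in place of 9 for gonadectomy in WT and KO, and 0 in place of 10 and of 3 for the interactions; 7, 6, 6 and 1 lists had an unadjusted p under 0.05 where it called 0.

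The score of female knockout genes in GDX males was 0.139 as a median (exact permutation p 0.0571) and 0.165 to 0.223 with single arrays left out. Within pairs it was 0.182 (0.080 to 0.249, all 4 positive). The exact p by sign changes was 0.125, the smallest that this test can give with 4 pairs. The score of KO sex genes after gonadectomy of WT was 0.463 with genes changed at least 2-fold (exact permutation p 0.0286) and 0.111 to 0.165 with single arrays left out, so it passed the threshold there and not as reported. Of the named genes, 8 values turned in sign, all close to 0. Prkar1a after gonadectomy of WT was 0.0053 with array weights, 0.080 with the adipocyte and 0.042 with the medulla covariate, and -0.072 to 0.044 with single arrays left out (0.0080 without WT intact male array 4, 0.044 without WT GDX array 4). Prkar1a in the interaction with sex was 0.026 with the medulla covariate, and Cyp11b2 was -0.51 to 0.031 in GDX males with single arrays left out (0.031 without WT GDX array 1) and 0.027 after gonadectomy of KO with the adipocyte covariate. For the 213 pairs of gene and comparison named, planned settings other than single arrays left 1856 of 1913 values on the same side of the threshold, took 51 below it and 5 past it. Single arrays did so for 1793 of 1918, 115 and 7, and the added settings for 455 of 514, 52 and 3. The median change of all genes stayed between -0.035 and 0.012 in every setting. Probe sets of low signal limit what can be called, since changes of genes under the filter were not tested, and at a log2 change of 0.5 the simulated interactions were called in 48% of genes.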

Other observations

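The tests of the interaction on the score of female knockout genes and the choice of the phosphodiesterase and heme oxygenase genes came only after the values were seen; the test of KO against WT GDX males on the sex genes was set before its value was seen.

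Phosphodiesterases, which break down the cyclic AMP that activates protein kinase A, differed with sex and with gonadectomy without passing as a list. Pde7a was higher in WT females than in WT males (1.61 ± 0.22, adjusted p 7.14e-05) and rose after gonadectomy of WT (1.23 ± 0.22, adjusted p 0.0031) and of KO males (1.11 ± 0.22, adjusted p 0.00221), but its second probe set barely moved (0.28, 0.08 and 0.10). Pde8b followed the same directions (0.59, 0.57 and 0.84; adjusted p 0.0019, 0.00605 and 6.73e-05), and Pde10a the opposite ones (-0.77, -0.80 and -0.70; adjusted p 0.0107, 0.0155 and 0.0132). Hmox1, heme oxygenase 1, was lower in WT females (-1.54 ± 0.16, adjusted p 2.3e-06) and fell after gonadectomy of WT (-1.44 ± 0.16, adjusted p 1.43e-05) and KO males (-1.32 ± 0.16, adjusted p 2.76e-05). The WT comparisons share the WT intact males, while gonadectomy of KO shares no array with the WT sexes. Between the WT sexes the call ended for Pde10a without WT intact male array 3 (adjusted p 0.0541), after gonadectomy of WT for Pde10a without WT intact male arrays 2 or 3 or WT GDX array 2 (adjusted p 0.0524 to 0.0646) and after gonadectomy of KO for Pde10a without KO intact male array 3 (adjusted p 0.0618). Of the list of PKA subunits and phosphodiesterases, the WT sexes gave 2 higher and 3 lower of 20, 2 and 5 adjusted over the list alone (camera adjusted p 0.629). After gonadectomy of WT 2 rose and 1 fell of 20, 2 and 4 adjusted over the list alone (adjusted p 0.924), and after gonadectomy of KO 3 rose and 3 fell of 20, 4 and 4 adjusted over the list alone (adjusted p 0.879).

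A hypothesis is that hormones of the testis may reduce the knockout response of the genes called in females. The knockout effect on their score was larger in GDX than in intact males by 0.14 ± 0.058, which misses the threshold (exact two-sided permutation p 0.112), so the question stays open. A further hypothesis, that the knockout moves gonadectomised males away from the female pattern of the WT sex genes, found no support. KO and WT GDX males differed by -0.0026 ± 0.030 (exact permutation p 0.886). With 4 arrays a group, a difference of the size of this error, or somewhat larger, could be missed.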
